A study of Mus musculus with 7 samples.

How the data were processed

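Gene expression was measured in sorted mouse spleen cells on Illumina MouseRef-8 single-colour bead arrays, 1 array per sample. Per the labels, the 7 samples came from C57BL/6J mice labelled female and 10 weeks old. They held 2 naive B cell samples from naive mice, gated as B220+ CD43-, and 5 samples taken at day 3 after lipopolysaccharide (LPS). The LPS samples were 3 plasmablast samples, gated as B220mid CD138+, and 2 plasma cell samples, gated as B220low CD138+. The labels number the replicates but do not say whether each came from a separate animal, so the p-values measure only the spread between these samples. The series also holds methylation sequencing, which was not analysed here.

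The deposited scanner table gave an intensity for each probe and array, in arbitrary fluorescence units with no normalization between arrays. Its lowest value was 101.8, so background had not been subtracted. The same deposited table gave a detection p-value for each probe and array, scored per the file headers against the array's own negative controls. Per the submitters' processing notes, signals were exported with GenomeStudio 2011.1. A second deposited table held an intensity that the authors had quantile normalized on the linear scale. This was checked by quantile normalizing the scanner values, which came within 0.0119 log2 units of the second table. The authors' normalized values served as an alternative only.

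Between 8817 and 9930 of 25697 probes were above background on each array (detection p under 0.01), or 34.3 to 38.6% of them. Median scanner signals ran from 153 to 186. Across arrays of the same group, Pearson's r over genes was at least 0.994, and differences between 2 such arrays had a standard deviation of 0.214 to 0.245 log2 units. The highest r between arrays of different groups was 0.828.

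Values were computed in R 4.3.3 with limma 3.58.1. The neqc function estimated background from the detection p-values by the normexp model, added an offset of 16, quantile normalized the 7 arrays and took log2. A table of the array's probes gave 1 gene symbol for 23978 probes and none for 1719. Symbols were brought up to date by Entrez number (23962 probes) through the RefSeq gene table of assembly GRCm38.p6, used for names only. Named probes above background on at least 2 arrays were kept (10113 probes). For each gene the probe with the highest mean over all arrays stood for the gene, which left 7425 genes, 1947 of them with more than 1 such probe. A probe's level depends on its sequence, so levels were compared between groups. The exception was the rank of Lyz2 among genes on the plasma cell arrays, which carries this limit. Levels are given as mean ± SD of the normalized log2 signal.

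A limma model with 3 group means was fitted to all 7 arrays (4 residual and 3.78 prior degrees of freedom), and eBayes tested 3 comparisons: plasmablasts against naive B cells, plasma cells against naive B cells, and plasma cells against plasmablasts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Where every array of the lower group lay below background, a fold is printed as "at least", measured up to the background limit of those arrays. The lowest signal above background was 6.27 to 6.79 on the 7 arrays.

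Before the data were examined, 26 gene lists (751 genes) were written down. Of these genes 644 had a named probe and 538 were tested. The lists covered sort markers, plasma cell genes, B cell genes, MHC class II presentation, the unfolded protein response, secretory translocation, endoplasmic reticulum (ER) to Golgi traffic, mitosis, DNA replication, DNA methylation machinery, Polycomb and histone modifiers, and the amino acid and integrated stress response. They also covered oxidative phosphorylation, glycolysis, cholesterol synthesis, ribosomal proteins, Toll-like receptor (TLR) and NF-kB signalling, the interferon response, homing and adhesion, apoptosis regulators, germinal center genes and immunoglobulin constant regions. The last lists held markers of T and NK cells, of myeloid cells, and of erythroid cells and platelets, and genes of sorting and dissociation stress. The 24 lists with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01, and again with a correlation estimated from the residuals. P-values were adjusted over the lists of each comparison, and member counts are given over all genes and adjusted over the list alone.

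The genes named in the text were fixed by a rule. They were the 5 largest rises and falls per comparison, ranked by normalized signal even below background, among called genes with no overlap between samples, up to 3 called members of each list by size of change, and a set of regulators of B cell identity, plasma cell identity and DNA methylation. A gene named outside this rule is said to be chosen after its values were seen.

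The pipeline was tested on simulated data built from these arrays, with 100 genes changed by 0.5 and 100 by 1 raw log2 unit. Plasmablasts against naive B cells recovered 62 and 95% of them, plasma cells against naive B cells 35 and 91%, and plasma cells against plasmablasts 50 and 97%. No recovered gene had the wrong direction. Of the calls, 6.55, 7.35 and 9.26% were of unchanged genes in the 3 tests. The changed genes were drawn from those with 1 probe, above background on all 7 arrays and of middle signal. The test therefore does not cover dim genes, and far fewer genes changed in it than were called in the data.

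Overlaps between comparisons that share arrays were set beside the count for independent lists and beside 100 draws of simulated groups without change. Alternatives changed the background step, offset, scaling, filter, probe rule, arrays in the fit, variance model, thresholds and the correlation in camera, used the replicate number as a block, or left out each array in turn. All 7 arrays lay on 1 chip with the groups in order of position, so position could not be separated from group.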

Results

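Sorted naive B cells, plasmablasts and plasma cells differed across most of the measured genes, and arrays of the same population matched each other closely. Of 7425 genes, limma called 5427 (73.1%) between plasmablasts and naive B cells, 5278 (71.1%) between plasma cells and naive B cells, and 5546 (74.7%) between plasma cells and plasmablasts. At this density of calls the size of a change and the gene group it belongs to say more than the count. Changes of at least 2-fold numbered 2448, 2317 and 2094.

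Plasmablasts at day 3 after LPS had turned on the program of antibody-secreting cells. Sdc1, the gene of the sort marker CD138, stood at 9.63 ± 0.15 (SD, n = 3) against 5.82 ± 0.09 (n = 2) in naive B cells, at least 8.58-fold higher. Prdm1, whose product Blimp-1 shuts down B cell genes, rose at least 5.70-fold, Irf4 rose 3.09-fold and Xbp1, which drives the secretory apparatus, rose 9.47-fold to 15.22 ± 0.06. The 5 largest rises by normalized signal, an order that bounded folds need not follow, were Bhlha15 (at least 76.6-fold), which encodes the secretory cell factor Mist1, Rsph1 (at least 50.6-fold), Derl3 (at least 46.9-fold), Rgcc (97.9-fold) and Pon3 (at least 35.7-fold). Tnfrsf17, the survival receptor BCMA, rose at least 38.0-fold. Of 23 measured plasma cell genes, 21 rose and 0 fell (22 and 0 adjusted over the list alone). Their median log2 change was 3.79, or 3.10 with bounded changes set at their limit (adjusted p = 2.94e-10, and adjusted p = 0.102 with an estimated correlation).

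The machinery that folds and moves secreted protein rose almost as a whole. In the unfolded protein response 23 of 25 genes rose and 1 fell (24 and 1 adjusted over the list alone, median 1.82). Edem1, which sends misfolded glycoproteins to degradation, rose 32.6-fold, Creld2 28.2-fold and the chaperone Hyou1 at least 15.4-fold. Secretory translocation showed 28 of 29 genes higher and 0 lower (the same adjusted over the list alone, median 1.95), among them the channel gene Sec61a1 (10.4-fold), Srprb (9.06-fold) and Ssr2 (8.31-fold). ER to Golgi traffic showed 31 of 32 higher and 0 lower (the same adjusted over the list alone, median 1.38), led by the coat gene Sec24d (at least 14.7-fold), the cargo receptor Lman1 (15.6-fold) and Kdelr3 (at least 4.17-fold). The 3 lists passed at adjusted p = 1.60e-09, 1.22e-10 and 2.30e-10, and had adjusted p = 0.102 with an estimated correlation. Amino acid supply moved with them: 23 of 25 genes of the amino acid and integrated stress response rose and 1 fell (the same adjusted over the list alone, median 1.97). This list passed at adjusted p = 1.82e-08 (adjusted p = 0.151 with an estimated correlation), with the asparagine synthetase gene Asns up at least 29.5-fold and Chac1 at least 13.2-fold.

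Plasmablasts were also in cycle. All 17 measured mitosis genes rose (17 adjusted over the list alone, median 3.46), including Cdk1 (15.6-fold), Top2a (14.7-fold) and the spindle gene Tpx2 (at least 6.04-fold). In DNA replication 29 of 32 genes rose and 2 fell (the same adjusted over the list alone, median 1.70), led by the nucleotide enzyme gene Rrm2 (19.3-fold), Mcm10 (19.0-fold) and Cdc6 (14.6-fold). Mitosis passed at adjusted p = 5.11e-09 and replication at adjusted p = 1.22e-08, both with adjusted p = 0.213 with an estimated correlation. The maintenance methyltransferase gene Dnmt1 rose 2.33-fold (adjusted p = 3.02e-06) and its partner Uhrf1 5.01-fold to 11.88 ± 0.10. Dnmt3b had a log2 difference of -0.22 (adjusted p = 0.227). Without either 1 of the 2 plasma cell arrays the same difference had adjusted p = 0.0437 and 0.0438, and over all alternatives its adjusted p ran from 0.0437 to 0.473. The DNA methylation machinery moved both ways, with 10 of 17 genes higher, 6 lower (the same adjusted over the list alone) and a median of 0.50 (adjusted p = 0.341). The demethylation-linked gene Gadd45g fell by 2.72 on the log2 scale.

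Energy and lipid genes changed less. Oxidative phosphorylation had 41 of 63 genes higher and 4 lower (the same adjusted over the list alone, median 0.41, adjusted p = 5.44e-05, and adjusted p = 0.151 with an estimated correlation), led by Atp5o (3.31-fold) and Atp5g1 (2.97-fold). Cholesterol synthesis had 12 of 15 higher and 1 lower (the same adjusted over the list alone, median 0.69, adjusted p = 0.00286, and adjusted p = 0.370 with an estimated correlation), with Lss at 4.21-fold. In glycolysis 8 of 15 rose and 3 fell (9 and 3 adjusted over the list alone, median 0.60, adjusted p = 0.141), the hexokinase gene Hk2 rising 8.12-fold while the glucose transporter gene Slc2a3 fell by 1.91. Ribosomal proteins had 2 of 51 higher and 9 lower (2 and 6 adjusted over the list alone, adjusted p = 0.532). Their median of -0.01 became 0.34 under 75th percentile scaling (adjusted p = 0.0220) and -0.22 under cyclic loess (adjusted p = 0.00816), in a range of adjusted p up to 0.653. Polycomb and histone modifiers were split, with 5 of 20 higher and 7 lower (the same adjusted over the list alone, median -0.07, adjusted p = 0.747). Ezh2, which writes H3K27 methylation, rose 2.95-fold and Cbx7 fell by 1.82.

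Naive B cell identity receded at the same time. Of 27 measured B cell genes, 24 fell and 2 rose (the same adjusted over the list alone, median -1.95, adjusted p = 6.52e-07, and adjusted p = 0.213 with an estimated correlation). Fcer2a, the gene of CD23, fell by 4.58 on the log2 scale, Klf2 fell by 3.47, and the complement receptor gene Cr2 was at least 6.50-fold lower. Bcl6, the repressor that opposes Prdm1, fell by 3.16 to 8.83 ± 0.13. Antigen presentation followed, with 13 of 14 MHC class II genes lower and 1 higher (the same adjusted over the list alone, median -2.20, adjusted p = 1.06e-04, and adjusted p = 0.213 with an estimated correlation). H2-Oa fell by 4.13, H2-DMb2 fell by 3.45 and H2-DMb1 fell by 3.39. In TLR and NF-kB signalling 21 of 26 genes fell and 4 rose (the same adjusted over the list alone, median -0.87, adjusted p = 4.58e-04, and adjusted p = 0.211 with an estimated correlation), among them Tlr1, which fell by 3.32, and Relb, which fell by 2.25. This list also holds the myeloid marker Cd14, with a log2 difference of -3.58. Of 18 myeloid markers 12 were lower and 2 higher, so RNA of macrophages on the naive B cell arrays may contribute to the fall of this list. The interferon response had 11 of 18 lower and 3 higher (the same adjusted over the list alone, median -0.93, adjusted p = 0.0482, and adjusted p = 0.486 with an estimated correlation). That result was borderline: its adjusted p ran from 0.00161 to 0.0765 over the alternatives and lay above 0.05 without any 1 of 6 arrays, reaching 0.0755 without naive B cell replicate 2.

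The naive B cell arrays also carried transcripts typical of red cells, platelets and macrophages, and these fell along with the genes above. Hba-a1, a hemoglobin gene, stood at 14.61 ± 0.32 in naive B cells and was at least 245-fold lower in plasmablasts, the largest fall by normalized signal. Fcna (at least 68.5-fold lower), Vcam1 (at least 78.1-fold), Rgs1 (at least 51.1-fold) and the complement gene C1qc (at least 47.9-fold) came next, and Fcna, Vcam1 and C1qc are made by splenic macrophages. Erythroid and platelet markers had 8 of 10 genes lower and 0 higher (the same adjusted over the list alone, median -3.31, or -1.80 with bounded changes at their limit, adjusted p = 2.97e-04, and adjusted p = 0.151 with an estimated correlation). Myeloid markers had 12 of 18 lower and 2 higher (the same adjusted over the list alone, median -2.64, adjusted p = 0.00110, and adjusted p = 0.270 with an estimated correlation). Sorting and dissociation stress genes had 18 of 21 lower and 2 higher (the same adjusted over the list alone, median -1.78, adjusted p = 1.32e-04, and adjusted p = 0.293 with an estimated correlation), such as Cd69 (-3.91). T and NK cell markers had 9 of 11 higher and 0 lower (the same adjusted over the list alone, median 1.14, or 0.55 with bounded changes at their limit, adjusted p = 0.00408, and adjusted p = 0.308 with an estimated correlation), with Thy1 up at least 2.81-fold and Cd3g at least 3.38-fold. Their median ran from 0.39 to 2.41 over the alternatives, the highest without plasma cell replicate 1 or 2, where fewer members stayed above background. The Y-linked gene Eif2s3y was also above background on the 2 naive B cell arrays and on 0 of 5 others.

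**Figure D1:**
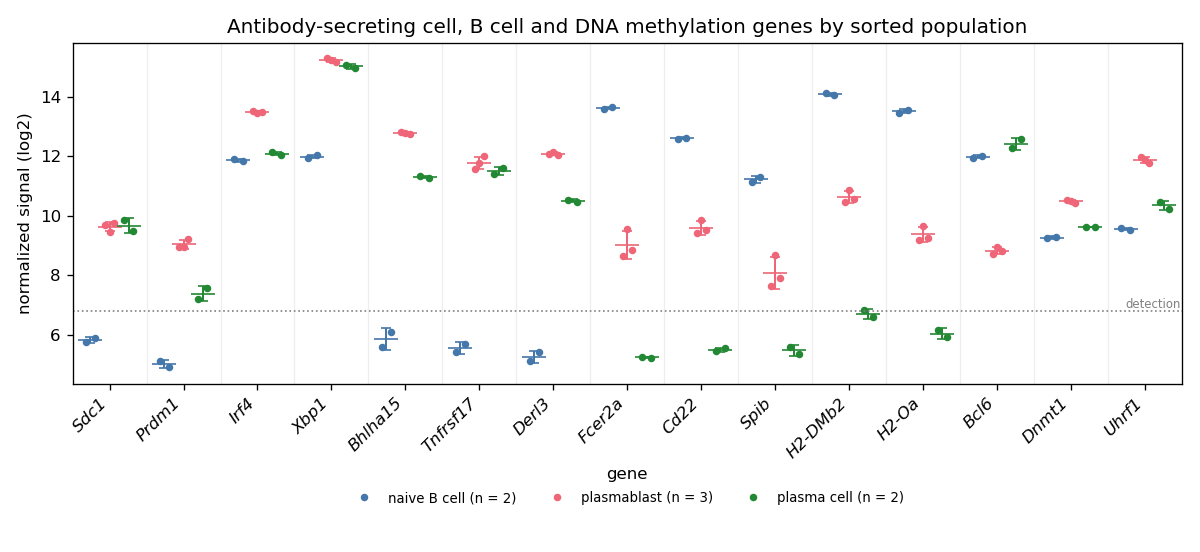
Normalized log2 signal of named genes on each array, for naive B cells (n = 2), plasmablasts (n = 3) and plasma cells (n = 2), with points for arrays, bars for mean and SD and a dotted line at 6.79, the highest of the arrays' lowest signals above background. Secretory genes such as Xbp1 (11.98, 15.22 and 15.01) rose in both LPS populations, while Fcer2a (13.61, 9.02 and 5.24) fell at each step.

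Plasma cells kept the secretory program, and most B cell genes stood lower than in plasmablasts. Sdc1 stood at 9.67 ± 0.26 (n = 2), at least 8.81-fold above naive B cells, and Xbp1 was 8.17-fold higher. Prdm1 was at least 1.81-fold higher, at 7.38 ± 0.25 against 5.02 ± 0.14, while Irf4 had a log2 difference of 0.22 (adjusted p = 0.0519, and 0.00636 to 0.188 over the alternatives). Of the plasma cell genes 20 rose and 2 fell (21 and 2 adjusted over the list alone, median 3.03, adjusted p = 8.77e-08, and adjusted p = 0.193 with an estimated correlation), with Tnfrsf17 at least 31.5-fold, Bhlha15 at least 27.4-fold and Derl3 at least 15.8-fold higher. The unfolded protein response had 21 genes higher and 3 lower (the same adjusted over the list alone, median 1.17), secretory translocation 23 and 0 (24 and 0 adjusted over the list alone, median 1.30) and ER to Golgi traffic 30 and 0 (31 and 0 adjusted over the list alone, median 0.75). These lists passed at adjusted p = 6.62e-06, 1.78e-07 and 1.12e-07, each with adjusted p = 0.193 with an estimated correlation. Creld2 rose 15.7-fold, the degradation gene Sel1l 13.3-fold, Sec61a1 4.73-fold and Lman1 7.40-fold. The amino acid and integrated stress response had 20 of 25 higher and 1 lower (the same adjusted over the list alone, median 1.01, adjusted p = 4.55e-06, and adjusted p = 0.193 with an estimated correlation), led by Nupr1 (at least 83.4-fold) and Asns (at least 16.8-fold). Nupr1 was also far above its plasmablast level, on the arrays on which 15 of 18 myeloid markers rose over plasmablasts. Its source was not tested.

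B cell genes fell further than in plasmablasts. In plasma cells 24 of 27 were lower than in naive B cells and 2 higher (the same adjusted over the list alone, median -2.86, adjusted p = 1.12e-07, and adjusted p = 0.193 with an estimated correlation). Fcer2a was at least 161-fold lower, Cd22, an inhibitory receptor gene, at least 80.2-fold, and Spib, a B cell transcription factor gene, at least 30.8-fold. MHC class II presentation had 12 of 14 lower and 1 higher (the same adjusted over the list alone, median -3.15, adjusted p = 4.82e-05, and adjusted p = 0.193 with an estimated correlation), including H2-Oa (at least 150-fold lower), H2-DMb2, which fell by 7.37, and the class II transactivator gene Ciita (32.1-fold lower). Hba-a1 (at least 321-fold lower) and Srpk3 (at least 60.0-fold lower) completed the 5 largest falls by normalized signal. Bcl6 stood at 12.42 ± 0.21, a log2 difference of 0.43 (adjusted p = 0.0167). That call was lost without naive B cell replicate 1 (adjusted p = 0.0768) or plasma cell replicate 2 (adjusted p = 0.101), within a range of 0.00199 to 0.101 over the alternatives.

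Cycle genes were raised less. Mitosis had 14 of 17 higher and 1 lower (the same adjusted over the list alone, median 1.57, adjusted p = 8.28e-05, and adjusted p = 0.351 with an estimated correlation), with Top2a at 4.27-fold and Cdc20 at 4.17-fold. DNA replication had 17 of 32 higher and 4 lower (the same adjusted over the list alone, median 0.37, adjusted p = 0.0646), and it passed without plasma cell replicate 2 (adjusted p = 0.00500, the lowest of a range that reached 0.106). Mcm10 rose 6.24-fold and the polymerase gene Pold1 fell by 2.51. Dnmt1 rose 1.28-fold (adjusted p = 0.00635) and Uhrf1 1.74-fold (adjusted p = 3.37e-04). Dnmt3b fell by 0.63 (adjusted p = 0.00954), a call lost without naive B cell replicate 1 (adjusted p = 0.0514, the highest of a range from 4.45e-04). Without plasma cell replicate 2 the difference was -0.35. DNA methylation machinery had 6 of 17 higher and 9 lower (the same adjusted over the list alone, median -0.38, adjusted p = 0.622), with Gadd45g down by a log2 difference of -2.36. Polycomb and histone modifiers had 2 of 20 higher and 12 lower (the same adjusted over the list alone, median -0.35, adjusted p = 0.0671), Cbx7 with -2.89 and Bmi1 with -1.68.

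Metabolic and signalling lists were mixed in this comparison. Glycolysis had 11 of 15 genes higher and 2 lower (the same adjusted over the list alone, median 0.57, adjusted p = 0.0174, and adjusted p = 0.193 with an estimated correlation), with the lactate transporter gene Slc16a3 up at least 6.05-fold. Slc16a3 was also higher than in plasmablasts, on the arrays on which 15 of 18 myeloid markers rose over plasmablasts, and its source was not tested. Oxidative phosphorylation had 22 of 63 higher and 7 lower (19 and 5 adjusted over the list alone, median 0.11, adjusted p = 0.153, with 0.0307 under 75th percentile scaling in a range up to 0.280). Cholesterol synthesis had 7 of 15 higher and 3 lower (the same adjusted over the list alone, median 0.04, adjusted p = 0.372). Ribosomal proteins had 18 of 51 lower and 0 higher (16 and 0 adjusted over the list alone, median -0.16, adjusted p = 0.0349, and adjusted p = 0.193 with an estimated correlation), among them Rpl22, which fell by 2.30. This call was lost without plasma cell replicate 1 (adjusted p = 0.0648) or 2 (adjusted p = 0.0992), and over the alternatives its adjusted p ran from 9.41e-07 to 0.0992. The interferon response had 13 of 18 lower and 2 higher (the same adjusted over the list alone, median -1.01, adjusted p = 0.0328, and adjusted p = 0.468 with an estimated correlation), a call lost without plasma cell replicate 2 (adjusted p = 0.0686, the highest of a range from 0.00755). Ifit3 fell by 3.39 and Isg20 rose 6.63-fold. TLR and NF-kB signalling was divided, with 11 of 26 higher and 9 lower (the same adjusted over the list alone, median 0.05, adjusted p = 0.595).

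The 5 largest rises in plasma cells by normalized signal were not genes of the secretory program. Saa3 (at least 314-fold) and Hp (at least 241-fold) encode acute-phase proteins, and Smpdl3b (at least 171-fold), Upp1 (at least 79.2-fold) and Rpl3l (at least 56.2-fold) followed. Markers of other cells rose beside them. Myeloid markers had 11 of 18 higher and 5 lower (the same adjusted over the list alone, median 1.94, adjusted p = 0.0588), with Csf3r up at least 19.6-fold and Vcam1 at least 102-fold lower. The list passed without naive B cell replicate 1 or 2 (adjusted p = 0.0128 and 0.00957) or plasmablast replicate 3 (adjusted p = 0.0437), within a range of 0.00957 to 0.376. T and NK cell markers had 10 of 11 higher and 0 lower (the same adjusted over the list alone, median 2.42, or 1.51 with bounded changes at their limit, adjusted p = 8.12e-05, and adjusted p = 0.193 with an estimated correlation), including Thy1 (at least 18.6-fold), Il7r (at least 13.3-fold) and Cd3g (at least 12.2-fold). Erythroid and platelet markers had 8 of 10 lower and 1 higher (the same adjusted over the list alone, median -3.02, adjusted p = 0.00179, and adjusted p = 0.193 with an estimated correlation), and stress genes 15 of 21 lower and 4 higher (the same adjusted over the list alone, median -1.90, adjusted p = 0.00634, and adjusted p = 0.425 with an estimated correlation).

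**Figure D2:**
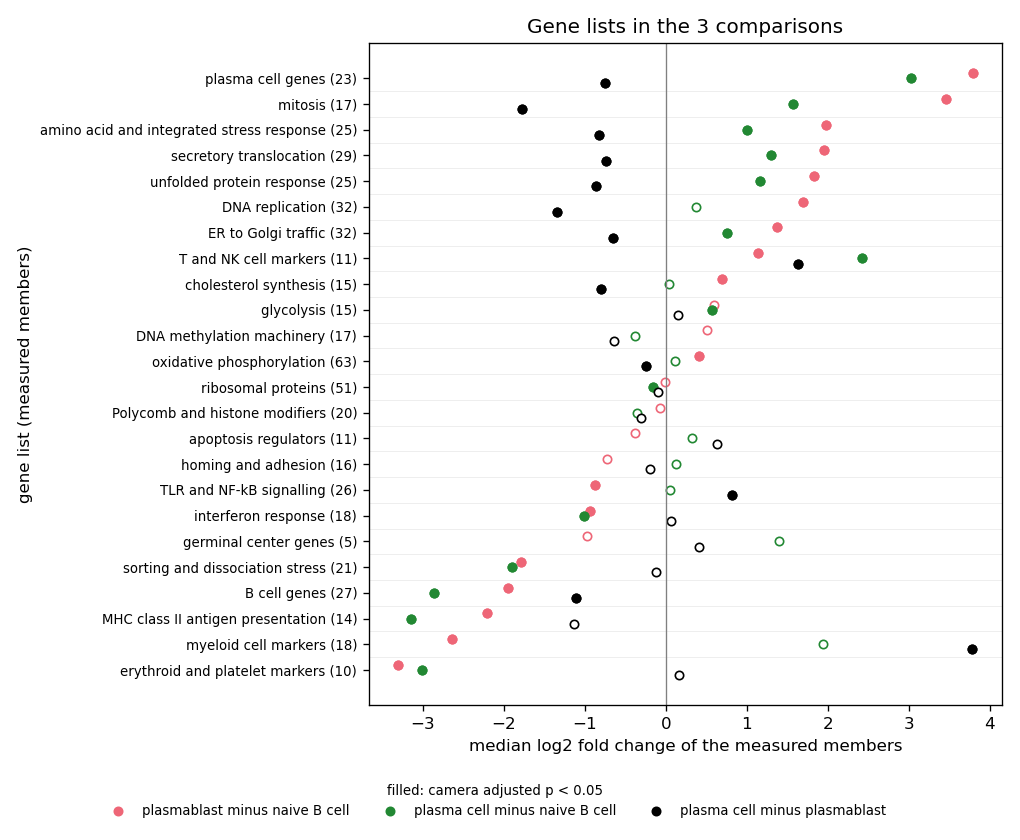
Median log2 fold change of the measured members of each gene list in the 3 comparisons, with filled points for lists at camera adjusted p under 0.05 and open points for the others. Plasma cell genes (3.79 and 3.03) and mitosis genes (3.46 and 1.57) were above naive B cells in both LPS populations and lower in plasma cells than in plasmablasts (-0.76 and -1.78), and medians near 0 changed sign under another scaling for ribosomal proteins (-0.01 to 0.34), erythroid and platelet markers (0.17 to -0.29), homing (-0.19 to 0.09) and stress genes (-0.12 to 0.16).

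From plasmablasts to plasma cells the cycle genes fell and the secretory genes eased. All 17 mitosis genes were lower (17 adjusted over the list alone, median -1.78, adjusted p = 6.60e-06), such as Aurka (-2.27), Plk1 (-2.07) and Cdk1 (-2.03). All 32 DNA replication genes were lower too (32 adjusted over the list alone, median -1.34, adjusted p = 1.39e-07), such as Cdc45 (-2.23), Mcm3 (-2.03) and Rrm2 (-1.78). Both lists had adjusted p = 0.349 with an estimated correlation. Uhrf1 fell by 1.53 and Dnmt1 fell by 0.86 (adjusted p = 2.98e-05), back toward their naive levels. Dnmt3b had a log2 difference of -0.41 (adjusted p = 0.0376). The call was lost in many alternatives, such as without plasma cell replicate 2 (-0.13, adjusted p = 0.280) and under cyclic loess (-0.17, adjusted p = 0.320), in a range from 0.00113 to 0.320. DNA methylation machinery had 12 of 17 lower and 3 higher (the same adjusted over the list alone, median -0.64, adjusted p = 0.161), with the base excision genes Ung (-1.67) and Mbd4 (-1.58) lower and Apobec1 3.18-fold higher. Among Polycomb and histone modifiers 11 of 20 were lower and 2 higher (the same adjusted over the list alone, median -0.31, adjusted p = 0.140), with Ezh2 at -1.34 and the H3K27 demethylase gene Kdm6b 3.70-fold higher. Apobec1 and Kdm6b rose on the same 2 plasma cell arrays on which 15 of 18 myeloid markers rose. Whether the sorted plasma cells themselves made more of either was not tested.

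Secretory lists fell by modest amounts from high plasmablast levels, on the same 2 plasma cell arrays on which 15 of 18 myeloid markers rose. RNA of other cells would lower the cycle, secretory, plasma cell and B cell lists together. The unfolded protein response had 23 of 25 genes lower and 0 higher (the same adjusted over the list alone, median -0.86), secretory translocation 29 of 29 (the same adjusted over the list alone, median -0.73) and ER to Golgi traffic 29 of 32 lower and 1 higher (the same adjusted over the list alone, median -0.65). They passed at adjusted p = 7.37e-05, 1.76e-05 and 1.70e-04, each with adjusted p = 0.269 with an estimated correlation. Hyou1 (-1.90), Ero1b (-1.68), Calr (-1.60) and Sec24d (-1.25) were among them. Plasma cell genes had 14 of 23 lower and 2 higher (17 and 2 adjusted over the list alone, median -0.76, adjusted p = 0.0169, and adjusted p = 0.352 with an estimated correlation), a call lost without plasma cell replicate 2 (adjusted p = 0.0590, the highest of a range from 2.36e-04). Prdm1 fell by 1.66, Irf4 fell by 1.40 and Derl3 fell by 1.57, but Xbp1 had -0.21 (adjusted p = 0.0532) and Sdc1 0.04 (adjusted p = 0.809). Xbp1 passed in some alternatives (adjusted p from 4.47e-04 to 0.225), and the difference of Sdc1 ran from -0.15 to 0.23, negative under 75th percentile scaling. The amino acid and integrated stress response had 20 of 25 lower and 3 higher (the same adjusted over the list alone, median -0.83, adjusted p = 0.00539, and adjusted p = 0.352 with an estimated correlation), with Shmt1 at -1.88 and Nupr1 at least 75.5-fold higher. Whether the sorted plasma cells themselves made more Nupr1 was not tested.

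B cell genes continued down, on the same 2 plasma cell arrays on which 15 of 18 myeloid markers rose. RNA of other cells would lower this list too, and its share of the fall was not tested. Of 27, 22 fell and 4 rose (the same adjusted over the list alone, median -1.11, adjusted p = 0.00510, and adjusted p = 0.419 with an estimated correlation). Vpreb3 (-4.33), Cd22 (at least 9.94-fold lower), Chst3 (-3.94), H2-DMb2 (-3.92) and Speer1 (-3.83) were the 5 largest falls by normalized signal, and Fcer2a was at least 6.69-fold lower. The 4 that rose included Bcl6 (a log2 change of 3.59, from 8.83 ± 0.13 to 12.42 ± 0.21) and Spi1 (13.5-fold), a factor that myeloid cells also make. Whether the sorted plasma cells themselves made more of either was not tested. MHC class II presentation had 10 of 14 lower and 2 higher (the same adjusted over the list alone, median -1.13, adjusted p = 0.0648), and passed in 5 alternatives, among them cyclic loess (adjusted p = 0.0222), the authors' values (adjusted p = 0.0447) and leaving out plasmablast replicate 1 (adjusted p = 0.0394), in a range of 0.00596 to 0.112. The share of higher genes among all calls was 38.4%, and under cyclic loess, which moved the median of all genes from -0.22 to -0.01, it was 52.5%. Among changes of at least 2-fold, 1175 were higher and 919 lower. In plasma cells against naive B cells cyclic loess moved the all-gene median from -0.08 to 0.09 and the share from 46.8 to 56.6%, and 1255 changes of at least 2-fold were higher and 1062 lower.

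Metabolic lists differed. Oxidative phosphorylation had 35 of 63 lower and 1 higher (30 and 1 adjusted over the list alone, median -0.24, adjusted p = 0.0119, and adjusted p = 0.349 with an estimated correlation). That call was lost under cyclic loess (median -0.08, adjusted p = 0.113) and without plasma cell replicate 2 (adjusted p = 0.0590), in a range from 7.74e-05 to 0.113. Cholesterol synthesis had 12 of 15 lower and 1 higher (the same adjusted over the list alone, median -0.80, adjusted p = 0.0220, and adjusted p = 0.444 with an estimated correlation), such as Sqle (-1.37) and Cyp51 (-1.36). It was lost without plasmablast replicate 2 (adjusted p = 0.0547) or plasma cell replicate 2 (adjusted p = 0.0568, the highest of a range from 0.00116). Ribosomal proteins had 12 of 51 lower and 0 higher (10 and 0 adjusted over the list alone, median -0.09, adjusted p = 0.26), and passed under 75th percentile scaling (median -0.55, adjusted p = 6.85e-05) and cyclic loess (median -0.11, adjusted p = 0.0273) in a range up to 0.573. Glycolysis had 5 of 15 higher and 4 lower (the same adjusted over the list alone, median 0.15, adjusted p = 0.293), with Slc16a3 at least 5.48-fold higher, on the arrays on which 15 of 18 myeloid markers rose.

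Myeloid markers rose from plasmablasts to plasma cells. The 5 largest rises by normalized signal were Clec4a1 (at least 115-fold), Rpl3l (at least 50.9-fold), Gcnt2 (at least 68.7-fold), Cd300ld (at least 64.8-fold) and Hp (149-fold), of which Clec4a1 and Cd300ld encode receptors of myeloid cells. Of 18 myeloid markers, 15 rose and 0 fell (the same adjusted over the list alone, median 3.78, or 2.56 with bounded changes at their limit, adjusted p = 1.39e-07, and adjusted p = 0.269 with an estimated correlation). Cd14 was at least 30.9-fold and the macrophage gene Adgre1 at least 30.3-fold higher, and Fcgr4 was 60.1-fold higher. Lyz2 stood at 15.33 in plasma cells against 10.00 in plasmablasts and 12.07 in naive B cells. Moving with these markers, TLR and NF-kB signalling had 17 of 26 genes higher and 3 lower (the same adjusted over the list alone, median 0.82, adjusted p = 2.31e-04, and adjusted p = 0.269 with an estimated correlation), with Irak3 up 8.33-fold, Tlr6 5.99-fold and Cd14, which both lists hold. T and NK cell markers had 7 of 11 higher and 2 lower (the same adjusted over the list alone, median 1.63, adjusted p = 0.00917, and adjusted p = 0.352 with an estimated correlation). That call was lost without plasma cell replicate 1 (median 1.06, adjusted p = 0.162) or 2 (median 0.98, adjusted p = 0.241), in a range from 0.00300 to 0.241.

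**Figure D3:**
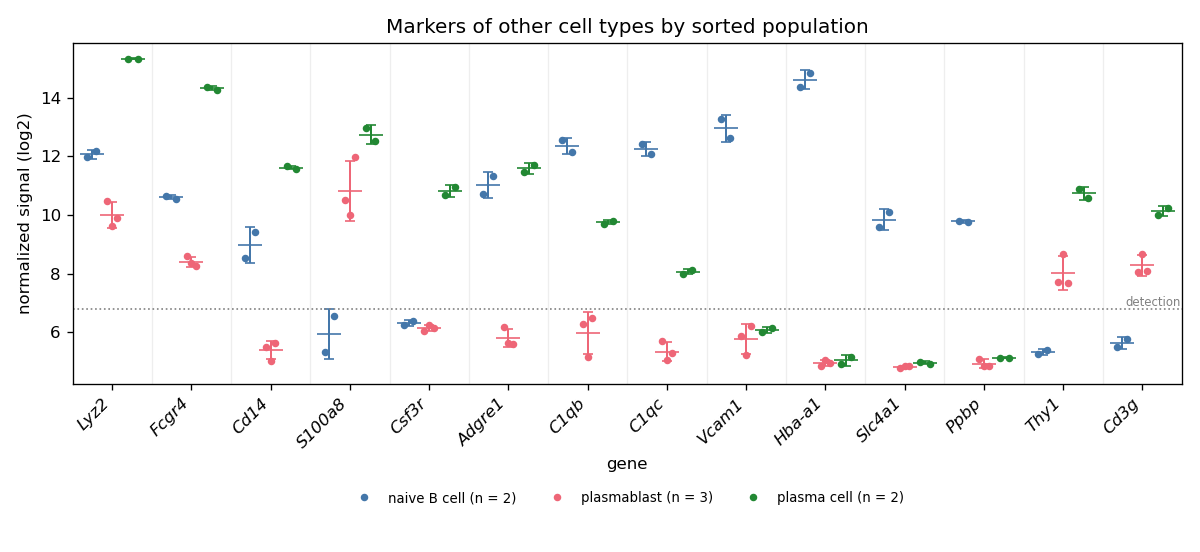
Normalized log2 signal of markers of other cell types on each array, for naive B cells (n = 2), plasmablasts (n = 3) and plasma cells (n = 2), with points for arrays, bars for mean and SD and a dotted line at 6.79, the highest of the arrays' lowest signals above background. Lyz2 (15.33) and Fcgr4 (14.32) were highest on the plasma cell arrays, and Hba-a1 (14.61) and Vcam1 (12.96) were highest on the naive B cell arrays.

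Calls of the 2 LPS populations against naive B cells overlapped. In both, 3238 genes moved the same way (1444 higher, 1794 lower), against 1933 for independent lists and 0 in simulated groups without change, where calls are rare by construction, and 810 moved in opposite directions against 1925 for independent lists. Xbp1, Bhlha15 and Tnfrsf17 were among the shared rises and Fcer2a, H2-Oa and Hba-a1 among the shared falls. The covariance of the 2 sets of log2 changes was 0.979, against 0.0104 from the noise of the shared naive B cell arrays. That noise was a small part of it, but the naive B cell levels themselves enter both sets. Pearson's r over genes was 0.531, against 0.548 in the simulated groups. That reference is set by the group sizes where all variance is noise, so it cannot decide how alike the populations are. Between single arrays, r was 0.813 to 0.827 for plasmablasts with plasma cells. It was 0.814 to 0.828 for plasmablasts with naive B cells and 0.797 to 0.800 for plasma cells with naive B cells. The overlap thus does not show that the LPS populations resemble each other more than plasmablasts resemble naive B cells. Along the order from naive B cell to plasmablast to plasma cell, 915 genes moved the same way at both steps (248 higher, 667 lower), against 2043 for independent lists and 0 simulated. Fcer2a, Cd22, H2-DMb2 and H2-Oa fell at both. Another 1947 genes rose and then fell, such as Cdk1, Rrm2, Uhrf1, Dnmt1, Prdm1 and Irf4, against 1206 for independent lists. In turn 1361 fell and then rose, such as Bcl6, Klf2 and the macrophage gene Adgre1, against 805. Of 18 myeloid markers 12 fell and 2 rose at the first step, and 15 rose and 0 fell at the second. RNA of other cells may thus make up a part of the 1361. The covariance of the steps was -0.794, against -0.00692 from the noise of the plasmablast arrays that both steps share with opposite sign. That noise was a small part of the covariance. Their r was -0.454, near the -0.400 that sharing arrays gave in simulated groups without change. Since r does not depend on the size of the changes, it cannot separate genes that turned back from the sharing. No conclusion is drawn from the excess over independent lists.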

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

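The tests of scaling for the myeloid and the red cell patterns were fixed before their results were seen, and all other tests in this part were chosen after seeing the result. In 172 genes the LPS populations moved apart, at least 2-fold lower in plasmablasts and at least 2-fold higher in plasma cells than in naive B cells. They include 5 of the 18 measured myeloid markers, against 172 of all 7425 genes. Clec4a1, Cd300ld, Tyrobp and Tlr13 (the last 2 chosen after their values were seen) have myeloid functions too. RNA of other cells on the naive B cell and plasma cell arrays could give this pattern, so it need not be a response of B cells. The reverse pattern held for 1 gene, Adam19, chosen after its values were seen, with log2 changes of 1.28 in plasmablasts and -1.07 in plasma cells. Among 605 probes above background without a gene name, 443, 415 and 428 were called in plasmablasts against naive B cells, plasma cells against naive B cells and plasma cells against plasmablasts, so a part of each response has no gene attached here.

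Myeloid genes were high on the plasma cell arrays. Another scaling does not account for this, since the median of the list, plasma cells over plasmablasts, was at least 2.21 under 75th percentile scaling, cyclic loess and the authors' values. RNA of neutrophils, monocytes or macrophages in the plasma cell samples may explain it, with 15 of 18 markers higher and Lyz2 at 15.33, at percentile 99.9 of the genes on both plasma cell arrays. A strict CD138+ gate without doublets would remove such cells if they lack CD138, although B220low alone would not. The purity of the sorted samples was not tested. Expression by the plasma cells themselves remains open, because the plasma cell list had a median of -0.76, lower as a mixture would give, while Sdc1 differed by 0.04 and Xbp1 by -0.21, or -0.74 under 75th percentile scaling. T and NK cell markers were higher than in naive B cells in both LPS populations, 10 of 11 in plasma cells and 9 of 11 in plasmablasts. The source of these transcripts was not tested, so the plasmablast arrays are not known to be free of other cells.

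Red cell, platelet and macrophage genes were high on the naive B cell arrays. Scaling is not the source, since the erythroid and platelet median, plasmablasts over naive B cells, was at most -1.74 under the same 3 scalings. RNA of red cells and platelets in the naive B cell samples may explain it, with 7 of 10 markers higher there than in both other groups and Hba-a1 at 14.61, Slc4a1 at 9.84 and Ppbp at 9.78. Of 18 myeloid markers 5 showed the same pattern, Vcam1 (12.96) and C1qb (12.35) among them. Sorting on B220 with doublets excluded would remove intact cells of these kinds but not free RNA.

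The sex-linked genes differed between groups that the labels all call female. Eif2s3y stood at 11.35 and Kdm5d at 8.45 on the naive B cell arrays, and Xist at 10.31 on the plasmablast and 9.61 on the plasma cell arrays. Scaling cannot make this, since Eif2s3y was above background on 0 of 5 arrays of the LPS groups by detection p-values, which no scaling touches. Male donors of the naive B cells would give the pattern of Eif2s3y, Kdm5d and Xist, which 7 of 7 arrays show. The probe of Uty, also Y-linked, departs from that pattern. It was above background on every array (7.25 in naive B cells, 6.86 in plasmablasts and 6.30 in plasma cells), and the reason was not tested. If the naive B cell donors were male, sex is confounded with LPS in both comparisons against naive B cells.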

How the results depend on the processing

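Requiring at least a 2-fold change gave 2448 genes for plasmablasts against naive B cells, 2317 for plasma cells against naive B cells and 2094 for plasma cells against plasmablasts, in place of 5427, 5278 and 5546. It left 5 of 13 lists in plasma cells against plasmablasts, 1181 of 3238 genes shared by the LPS populations, and 132 of 915 genes with the same direction at both steps. An adjusted p under 0.01 left 569 of those 915. By construction, these thresholds drop small changes. With an estimated correlation, camera called 0, 0 and 0 lists in the 3 comparisons in place of 17, 14 and 13. Ribosomal proteins in plasmablasts reversed, from a median of -0.01 to 0.34 under 75th percentile scaling, and the cause was not tested. Leaving out 1 array at a time gave 4702 to 5334, 4509 to 5214 and 4721 to 5391 called genes. The doubted arrays make up whole groups, so no count could be made without them together. With the replicate block the counts were 5278, 5227 and 5385, and 5244 for the block over the LPS arrays alone. The labels share only a number: deviations of arrays with the same number correlated by 0.17 at most. Of the values of named genes under the alternatives, 5415 kept their call status, 18 gained a call, 44 lost one and 0 reversed as calls, while Sdc1 between the LPS populations, not called, changed sign in some.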

Other observations

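Tests in this part were computed with the rest, and which of them to describe was chosen after seeing the result. Of the sort marker genes, Sdc1 followed the CD138 gate. Ptprc, whose probe cannot tell the B220 isoform from other forms of CD45, fell by 0.69 in plasmablasts (adjusted p = 0.00426), had a log2 difference of 0.19 in plasma cells against naive B cells (adjusted p = 0.353, with 0.60 and adjusted p = 0.0101 for the mean of its probes, in a range up to 0.826) and rose by 0.88 from plasmablasts to plasma cells. Spn, the gene of CD43, rose 1.61-fold in plasmablasts and 2.30-fold in plasma cells against naive B cells, and 1.43-fold between them (adjusted p = 0.0101), a call lost without plasma cell replicate 1 (a log2 difference of 0.31 in place of 0.51, adjusted p = 0.0792, the highest of a range from 8.03e-04). The rises of Ptprc and Spn from plasmablasts to plasma cells were on the arrays on which 15 of 18 myeloid markers rose, and their source was not tested. Of 3 sort markers, 2 rose and 1 fell in plasmablasts, and 2 rose and 0 fell in each plasma cell comparison (the same adjusted over the list alone).

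Apoptosis regulators did not pass as a set in any comparison, while single members changed. In plasmablasts Bcl2l1, which encodes the survival protein Bcl-xL, rose 7.38-fold over naive B cells while Bcl2a1d fell by 2.65. From plasmablasts to plasma cells Bcl2a1d rose 18.3-fold, Bcl2 4.82-fold and the death gene Pmaip1 5.46-fold, on the arrays on which 15 of 18 myeloid markers rose. Apoptosis regulators had 2 of 11 higher and 6 lower in plasmablasts (median -0.38, adjusted p = 0.379), 5 and 2 in plasma cells against naive B cells (median 0.33, adjusted p = 0.185), and 7 and 3 between the LPS populations (median 0.63, adjusted p = 0.0761), the same adjusted over the list alone. The last list passed without plasma cell replicate 1 (adjusted p = 0.0493, in a range of 0.00635 to 0.133).

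Germinal center genes did not move as a set. Mef2b rose 8.11-fold in plasmablasts and 3.14-fold in plasma cells over naive B cells, Gpr183, a guidance receptor gene, fell by 2.00 and fell by 3.47, and Fas rose 7.45-fold from plasmablasts to plasma cells. Of 5 measured genes 2 were higher and 3 lower in plasmablasts (median -0.98, adjusted p = 0.574), 4 and 1 in plasma cells against naive B cells (median 1.39, adjusted p = 0.175), and 3 and 2 between the LPS populations (median 0.41, adjusted p = 0.346), the same adjusted over the list alone.

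Homing genes did not move as a set, while single receptors changed. Ccr7, which guides cells to T zones, fell by 3.96 in plasmablasts and was at least 28.2-fold lower in plasma cells, Cxcr3 rose at least 2.96-fold in plasmablasts, and the integrin genes Itgb7 (7.69-fold) and Itgb2 (7.65-fold), which myeloid cells also make, rose from plasmablasts to plasma cells, as did 15 of 18 myeloid markers. The list had 4 of 16 higher and 9 lower in plasmablasts (median -0.73, adjusted p = 0.234). In plasma cells against naive B cells 8 were higher and 7 lower. There the median was 0.13, or -0.05 with bounded changes at their limit, the mean -0.58 and the camera direction down (adjusted p = 0.879). Between the LPS populations 7 were higher and 8 lower, with a median of -0.19, or 0.09 under cyclic loess, a mean of 0.13 and the camera direction up (adjusted p = 0.580). All these counts were the same adjusted over the list alone.

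The interferon response was divided between the LPS populations, with 8 of 18 higher and 8 lower (median 0.06, or -0.02 with bounded changes at their limit, mean -0.01, camera up, adjusted p = 0.563), Oasl2 rising at least 2.32-fold and Oasl1 falling (-2.03). Stress genes had 6 of 21 higher and 6 lower (median -0.12, or 0.16 under cyclic loess, mean 0.39, camera up, adjusted p = 0.530), with Klf4, which myeloid cells also make, at least 32.6-fold higher. Erythroid and platelet markers had 3 of 10 higher and 1 lower (median 0.17, or -0.29 under 75th percentile scaling, adjusted p = 0.254), the transferrin receptor gene Tfrc falling (-1.23). These counts were the same adjusted over the list alone.

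Several genes central to the process could not be followed. Of 20 immunoglobulin constant region genes 3 had a named probe and 0 were above background on 2 arrays. Bach2, Tet1 and Tet2 had no named probe, and the probes of Pax5, Dnmt3a and Tet3 were above background on 0 arrays. For 55, 45 and 24 genes in the 3 comparisons, called probes of the same gene pointed in opposite directions.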
